A study of Homo sapiens with 10 samples.

How the data were processed

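The samples were H9 human embryonic stem cells grown on mouse embryonic fibroblast feeders with basic FGF and serum replacement, transduced with GFP or GFP-PRDM1 vectors and collected at days 7 and 17. Per the labels, total RNA was purified on spin columns and 1 ug was labelled with biotin by the Affymetrix 3' IVT Express procedure. The deposited values are in log2 units, in a single table of 54613 probe sets and 10 arrays. The base of the logarithm was taken as 2 and, like the method of probe set summarisation and of normalization between arrays, is not given in the sources used here. The values themselves show that each probe set was centred on its median over the 10 arrays, since all 54613 medians were within 1e-06 of 0. Array medians were within 0.0247 of 0, and no arrays held identical values.

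Probe sets were annotated with gene symbols, and symbols were updated by gene identifier from an annotation table of the human genome, which matched 41037 of the 41091 probe sets with 1 symbol. Of the probe sets, 1801 had several symbols and 11721 had no gene in the annotation, and both kinds were left out of the gene tests. Of a gene's probe sets, 2411 ending in _x_at were left out where others remained, which left 38680 probe sets for 19775 genes, 9839 of them with 1 probe set and 9936 with several. The rule written before the data were examined chose the probe set with the highest mean and filtered dim ones at the 40th percentile. Centring removes signal levels, so neither has its intended meaning, and each gene was instead the mean of its probe sets with no filter.

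Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group fitted to all 10 arrays and moderated by eBayes. The comparisons were GFP-PRDM1 against GFP at each day, the difference between those effects, and day 17 against day 7 within each vector. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes, 2-sided, and a second count asked for a log2 fold change of at least 1. Error values of fold changes are standard errors of the fit.

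The 17 gene lists, of 409 named members of which 366 were matched, were core pluripotency, early germ cell, late germ cell and meiosis, neural, primitive streak and mesoderm, endoderm, trophoblast and amnion, stromal and extracellular matrix, cell cycle, p53 targets and apoptosis, PRDM1-repressed genes of B cells, interferon response, DNA and histone methylation, HOX, epithelial, WNT, BMP and NODAL targets, and housekeeping. Lists were tested against all other genes by camera with a preset correlation of 0.01, beside camera with an estimated correlation and fry, and adjusted over the lists of a comparison. PRDM1 was left out of the lists because the vector carries it. The named genes are PRDM1 with every probe set and array, 12 germ cell, pluripotency and neural genes always given, the 8 largest increases and decreases per day among genes passing the test whose groups do not overlap, up to 4 passing members per list and day, and up to 5 per direction in the other comparisons. Of the 12, POU5F1 and DPPA3 were not analysed here.

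Whether replicate numbers pair the arrays was checked on deviations from the group means, since the labels do not say so. At day 17, arrays with the same number in both vectors correlated at 0.34, 0.50 and 0.26, against values between -0.38 and 0.05 for different numbers. Deviations within a group cancel out, so positive values for the same numbers by themselves bring lower ones for different numbers. The numbers thus appear to pair these samples. The main day 17 results are from the fit without pairing, and results with replicate number as a block stand beside them. At day 7 the value was 0.094, from 2 pairs, and across days it lay between -0.095 and 0.095.

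The method was tested on simulated data in 10 runs with 200 changed genes each. At day 7, 10.6%, 79.3% and 97.3% of changes of 0.5, 1 and 2 were recovered, with 4.52% false calls. At day 17 these were 31.3%, 89.9% and 99.2%, with 5.68% false calls, and for the difference between days 1.49%, 50.1% and 93.5%, with 5.03%. A 20-gene list shifted by 0.5 was found in 10 of 10 runs at each day, and an unshifted one in 0. The simulated genes varied independently, without pairing or batch, whereas estimated correlations within the real lists reached 0.57. These runs therefore do not test camera calls on lists whose genes vary together.

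Alternatives tried were quantile normalization, centring each array on its median, a filter at the 60th percentile, other choices of probe set, eBayes with trend and robust settings, array quality weights, only the groups compared, replicate number as a block and leaving out each array in turn. The eBayes trend follows each gene's mean over the arrays, which after centring is no signal level. Calls lost with it therefore do not show what low signal would do. Chosen after the data were seen were the highest-mean and largest-SD probe sets, the 40th percentile filter on the centred values, each probe set tested separately, a term separating replicate 1 of day 17 from replicates 2 and 3, the day 17 comparison by either part alone, the day 7 values of CGA, ERVW-1 and ERVFRD-1 without each array, and the lists for hypoxia response, amnion, syncytiotrophoblast, extravillous trophoblast, cytotrophoblast, and immunoproteasome and antigen presentation. Pseudocounts do not apply to log values, and with no filter as the main setting the no-filter alternative is the main result. The table holds 0 Affymetrix control probe sets, so the check of 3' against 5' control signal was not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.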

Results

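Human embryonic stem cells of the established H9 line received either a control vector (GFP) or a vector named GFP-PRDM1, and their total RNA was measured on Affymetrix 3' expression arrays at days 7 and 17. PRDM1, also called BLIMP1, is a transcriptional repressor required for the specification of primordial germ cells and for the differentiation of plasma cells. The 10 arrays fell into 4 groups, with 2 GFP and 2 GFP-PRDM1 arrays at day 7 and 3 GFP and 3 GFP-PRDM1 arrays at day 17. The study's question was whether cells carrying GFP-PRDM1 have an expression profile like that of the germline. Values were available for 54613 probe sets, each centred on its own median over the 10 arrays, so that they show differences between arrays and no signal level. Of these, 38680 probe sets stood for 19775 genes. Array medians ranged from -0.0247 to 0.0164 on the log2 scale. The labels call the arrays of a group biological replicates without saying whether the vectors were delivered separately, so p-values measure the spread between these samples, and their number limits the precision.

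The signal of PRDM1 itself differed between its probe sets and between days. The labels do not give the vector's sequence, so whether a probe set reads the vector's transcript, that of the cells' own gene or both is not known. At day 7 the probe set 217192_s_at lay at 1.44 ± 0.07 (SD, n = 2) in GFP-PRDM1 cells and at -0.19 ± 0.18 (SD, n = 2) in GFP cells, a log2 difference of 1.64 (SE 0.13, adjusted p = 0.000908). The single GFP-PRDM1 arrays of day 7 stood at 1.49 and 1.39, and the GFP arrays at -0.06 and -0.32. At day 17 the same probe set lay at 0.10 ± 0.10 (SD, n = 3) in GFP-PRDM1 cells and at -0.09 ± 0.10 (SD, n = 3) in GFP cells, and the difference of 0.19 did not pass (adjusted p = 0.460). The GFP-PRDM1 arrays of day 17 stood at 0.19, -0.01 and 0.11 and the GFP arrays at -0.20, -0.07 and 0.01. The change in this difference from day 7 to day 17 was -1.45 (SE 0.17, adjusted p = 0.0512) and narrowly missed the threshold. Neither of the other two probe sets passed: 228964_at differed by 0.81 at day 7 (adjusted p = 0.480) and 0.01 at day 17 (adjusted p = 0.994), and 235668_at by 0.50 (adjusted p = 0.304) and -0.28 (adjusted p = 0.528). Averaged over its probe sets, PRDM1 differed by 0.98 at day 7 (adjusted p = 0.0654, but 0.0230 with array quality weights and 0.0166 with only the day 7 groups in the fit) and by -0.03 at day 17 (adjusted p = 0.961).

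**Figure D1:**
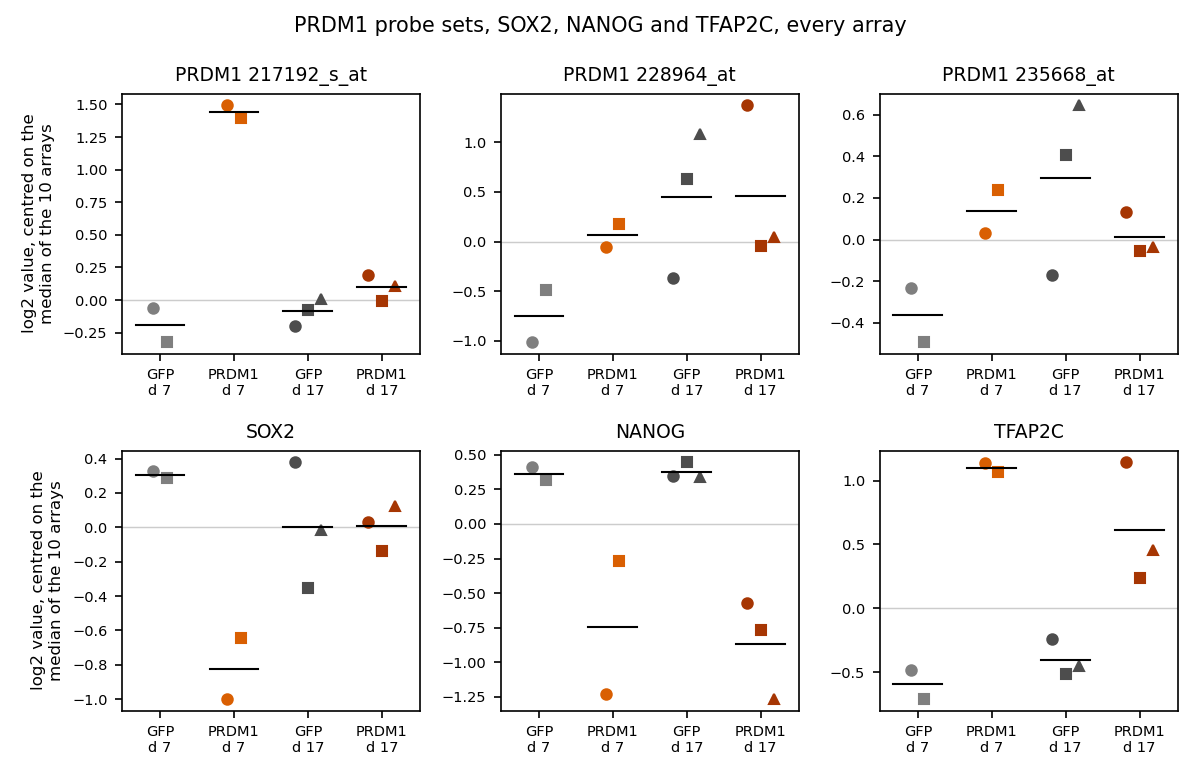
Log2 values (vertical axis, own scale per panel) of the PRDM1 probe sets, SOX2, NANOG and TFAP2C in the 4 groups (PRDM1 on the axis stands for GFP-PRDM1, d for day), with a symbol per array (circle, square and triangle for replicates 1, 2 and 3) and a line at the group mean. In the panel of probe set 217192_s_at the GFP-PRDM1 arrays of day 7 stand at 1.49 and 1.39, and all other arrays lie between -0.32 and 0.19.

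At day 7, the trophoblast and amnion list had the largest mean change of the 17 lists, 2.59 (camera adjusted p = 1.66e-20, and adjusted p = 0.206 with an estimated correlation). S100P, a calcium-binding protein abundant in placenta, rose by 6.24 on the log2 scale (SE 0.32, adjusted p = 0.000185, n = 2 and 2), and GATA3, a transcription factor of trophoblast and amnion, by 4.81 (SE 0.64, adjusted p = 0.00605). Of the 21 measured trophoblast and amnion genes, 15 rose and 0 fell over all genes tested by limma, and 19 rose when adjusted over the list alone. VTCN1 rose by 4.62, ENPEP by 4.58 and IGFBP3 by 4.29. Among pluripotency genes, SOX2, a core transcription factor of pluripotent and neural progenitor cells, fell by 1.13 (SE 0.22, adjusted p = 0.0208), while the change in NANOG, -1.11 (SE 0.29, adjusted p = 0.0626), did not pass. It was -1.59 and passed without GFP-PRDM1 replicate 2 (adjusted p = 0.0111), was -0.63 without GFP-PRDM1 replicate 1 (adjusted p = 0.315), and passed with array quality weights (adjusted p = 0.0300).

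In all, 1074 of 19775 genes changed at day 7, of which 602 rose and 472 fell, and 463 of them changed by a log2 fold change of at least 1. Other large increases were those of TCIM (5.52), the melanin-synthesis enzyme TYRP1 (5.43), the keratin KRT23 (5.36), the epidermal transcription factor ZNF750 (5.08), the hydroxycarboxylic acid receptor HCAR3 (5.07) and KANK4 (4.95). The largest decreases were those of the noncoding RNAs LINC01844 (-4.13) and JAKMIP2-AS1 (-2.95), the tryptophan-degrading enzyme IDO1 (-2.83), the planar cell polarity gene PRICKLE1 (-2.55), the immunoproteasome subunit PSMB9 (-2.47), the secreted WNT inhibitor WIF1 (-2.30), the homeobox gene HESX1 (-2.23) and MRAP2 (-2.08). For each of these genes every GFP-PRDM1 array lay beyond every GFP array, as the rule that chose them required. Epithelial genes also rose, with KRT8 at 2.59, KRT18 at 1.97, CLDN4 at 1.64 (probe sets at 3.25 and 0.02) and RAB25 at 1.30. Of the 17 epithelial genes, 5 rose and 0 fell over all genes, and 7 rose when adjusted over the list alone. Without GFP replicate 1 the day 7 count was 106 genes (83 rose), without GFP replicate 2 it was 164 (90 rose), and without GFP-PRDM1 replicate 1 it was 189 (131 rose). Without each array, 12 of the 45 named calls (S100P, KRT23, TYRP1, ZNF750, HCAR3, ENPEP, IGFBP3, CLDN4, LINC01844, JAKMIP2-AS1, WIF1 and MRAP2) were kept. SOX2 kept a fold change between -0.95 and -1.30 without each array, but its adjusted p was 0.139, 0.104 and 0.153 without those same arrays and 0.0276 without GFP-PRDM1 replicate 2. With eBayes trend and robust settings the day 7 calls of PRICKLE1, HESX1, PRDM14, TFCP2L1, PDPN, ISL1, TET2, KRT8 and ID2 were lost (adjusted p = 0.0587 to 0.301). The trend there follows the mean of centred values, which holds no signal level.

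At day 17, hormone and syncytin genes of the placenta were among the largest increases. CGA, the common alpha subunit of the glycoprotein hormones, rose by 5.44 (SE 0.59, adjusted p = 0.00316, n = 3 and 3), the mean of probe sets at 7.69 and 3.19. The syncytin genes ERVW-1 and ERVFRD-1, whose envelope proteins fuse trophoblast cells, rose by 5.40 (SE 0.50, adjusted p = 0.00208) and 4.54 (SE 0.42, adjusted p = 0.00208). They had also risen at day 7, CGA by 3.13 (adjusted p = 0.0403, probe sets at 5.40 and 0.85), ERVW-1 by 3.11 (0.0234) and ERVFRD-1 by 2.30 (0.0364). The difference between the days did not pass for these genes. The day 7 calls of all 3 were lost without any 1 array other than GFP-PRDM1 replicate 2 (adjusted p = 0.128 to 0.231), and without GFP-PRDM1 replicate 1 the changes were 1.96, 2.23 and 1.61. For CGA the GFP-PRDM1 arrays of day 7 stood at 3.15 and 0.81. S100P rose by 5.26 (SE 0.26, adjusted p = 0.000138). Of the 21 trophoblast and amnion genes, 15 again rose and 0 fell over all genes tested by limma, and 17 rose when adjusted over the list alone. The collagen gene COL15A1, which is in none of the lists, rose by 5.35 (SE 0.31, adjusted p = 0.000239). Its call was lost with eBayes trend and robust settings (adjusted p = 0.0897), where the trend follows centred means and no signal level. In the stromal list the collagen genes COL6A3 (4.34) and COL3A1 (3.98) and the matrix protein genes TGFBI (3.63) and POSTN (2.46) rose. Whether RNA of the mouse feeder cells contributed to the collagen and matrix signals was not tested. Of the 22 stromal and extracellular matrix genes, 11 rose and 0 fell over all genes, and 14 rose and 1 fell when adjusted over the list alone. In the pairs of replicates 1, 2 and 3 the mean effect was 3.67, 2.34 and 2.15 on the trophoblast list and 1.75, 1.22 and 1.28 on the stromal list. NANOG, a core pluripotency transcription factor, fell by 1.25 (SE 0.24, adjusted p = 0.0339).

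In all, 429 of 19775 genes changed at day 17, of which 353 rose and 76 fell, and 234 changed by at least 1. The GABA receptor subunit GABRP rose by 5.12, KRT23 by 5.10, TCIM by 4.70 and the B7-family protein VTCN1 by 4.63. Beyond NANOG, the largest decreases were those of LINC02582 (-1.72), the lymphocyte kinase LCK (-1.65), the calcium-binding protein CALB1 (-1.54), CLTRN (-1.50), the small GTPase RAP1A (-1.42), the plasma prekallikrein gene KLKB1 (-1.27) and LINC01844 (-1.26). With replicate number as a block, 634 genes changed, and the calls of CALB1 (adjusted p = 0.0529), IFITM1 (0.0544) and FABP7 (0.0626) were lost. With eBayes trend and robust settings those of COL15A1, TCIM, CLTRN, LINC01844, NANOG, TFAP2C, PAX6, IFITM1, LHX2, ISL1 and IRF9 were lost (adjusted p = 0.0509 to 0.319). Without GFP replicates 1, 2 and 3 in turn the count was 774, 207 and 157, and without GFP-PRDM1 replicates 1, 2 and 3 it was 230, 165 and 280. The share that rose was 82.3% of the 429 genes and 84.8% to 94.6% without each array, except for 56.7% (439 rose and 335 fell) without GFP replicate 1. It was 63.0% with array quality weights (583 and 343) and 61.8% by replicates 2 and 3 alone (291 and 180). Without each array 17 of the 37 named calls were kept: CGA, CLDN4, CLTRN, COL15A1, DSP, ERVFRD-1, ERVW-1, GABRP, IFI6, IRF9, KRT23, POSTN, RAP1A, S100P, SOX7, TGFBI and VTCN1. COL6A3 and TCIM each lost theirs without 4 of the 6 arrays (adjusted p = 0.0534 to 0.0759 and 0.0617 to 0.0991) and COL3A1 without 3 (0.0533 to 0.0663). Some of these means joined unlike probe sets. For RAP1A, 1 of 3 probe sets differed by -4.03 and the other two by -0.22 and 0.00, and for POSTN 2 differed by 4.18 and 5.45 and the other two by 0.20 and -0.01. For COL3A1, 215077_at differed by 0.02 and the others by 3.89, 5.80 and 6.21, and the lowest probe sets of FABP7 and CLDN4 differed by -0.18 and -0.05.

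Germ cell genes as a group moved neither way together by camera or by fry at either day (smallest fry adjusted p = 0.240). In the early germ cell list, 3 of 22 genes rose and 1 fell at day 7 (4 and 2 when adjusted over the list alone), with a mean log2 change of 0.05 (camera adjusted p = 0.459), which ran from -0.04 to 0.14 without each array in turn. In that list 1 gene rose and 1 fell at day 17 (1 and 1 over the list alone), with a mean of -0.15 (adjusted p = 0.784, and -0.23 to -0.10 without each array). TFAP2C, a transcription factor shared by primordial germ cells and trophoblast, rose by 1.70 at day 7 (adjusted p = 0.00859) and by 1.02 at day 17 (adjusted p = 0.0414). Its day 7 adjusted p was 0.0665 and 0.0700 without GFP replicates 1 and 2 and 0.0661 without GFP-PRDM1 replicate 1, and its day 17 adjusted p was 0.128 and 0.123 without GFP replicates 2 and 3 and 0.0772 without GFP-PRDM1 replicate 3. TFCP2L1 (0.90) and PDPN (0.62) also rose at day 7, whereas PRDM14, a regulator of germ cell and pluripotent identity, fell by 1.60 (adjusted p = 0.0475). The antiviral membrane protein gene IFITM1 fell by 0.91 at day 17. In the late germ cell and meiosis list, 1 of 38 genes rose and 0 fell at day 7, the piRNA-pathway gene PIWIL4 by 1.51 (adjusted p = 0.0178), the same over the list alone. The mean was -0.12 (camera adjusted p = 0.461, and -0.18 to -0.06 without each array). At day 17 none of the 38 passed in limma, over all genes or over the list alone, where 3472 of all genes had an unadjusted p under 0.05. The mean at day 17 was -0.08 (camera adjusted p = 0.438, and -0.10 to -0.05 without each array).

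Single germ cell regulators gave the following values. SOX17, an early regulator of human germ cells and endoderm, differed by 0.84 at day 7 (adjusted p = 0.779) and by -2.19 at day 17 (SE 1.02, adjusted p = 0.308). At days 7 and 17 in turn SOX17 lay at -0.34 and 2.31 (SD 2.57 at day 17) in GFP cells. In GFP-PRDM1 cells it lay at 0.51 and 0.12, so the negative day 17 value came from higher, uneven GFP arrays. Without GFP replicate 1 the day 17 value of SOX17 was -3.67 (adjusted p = 0.00211), and with array quality weights it was -3.29 (adjusted p = 0.0436). The RNA-binding protein gene DAZL differed by -2.22 at day 7 (SE 0.74, adjusted p = 0.124) and by 0.29 at day 17 (adjusted p = 0.839), and without that array its day 17 value was 1.17 (adjusted p = 0.0165). The day 7 value of DAZL passed with array quality weights (adjusted p = 0.0333) and with only the day 7 groups in the fit (0.0112). NANOS3 differed by 0.13 (adjusted p = 0.775) and 0.00 (adjusted p = 0.990), the receptor KIT by -0.42 (adjusted p = 0.173) and -0.04 (adjusted p = 0.909), and the helicase DDX4 by 0.31 (adjusted p = 0.354) and -0.13 (adjusted p = 0.655), at days 7 and 17 in turn. POU5F1 and DPPA3 were not analysed here.

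Pluripotency genes had negative means at both days. Of 20 genes in the core pluripotency list, 4 fell and 0 rose at day 7 (9 fell when adjusted over the list alone), among them the forkhead transcription factor FOXD3 (-1.25, with probe sets at -2.10 and -0.41) and the DNA methyltransferase DNMT3B (-1.17). At day 17, 1 fell and 0 rose (6 fell over the list alone). The list means were -0.63 at day 7 (camera adjusted p = 8.48e-05) and -0.65 at day 17 (adjusted p = 0.000435), and the adjusted p was 0.329 and 0.326 with an estimated correlation. At day 7, GFP-PRDM1 replicates 1 and 2 stood at -0.54 and -0.03 on this list, and the GFP arrays at 0.36 and 0.33. SOX2 differed by 0.00 at day 17 (95% confidence interval -0.39 to 0.40, adjusted p = 0.996). The difference between its effects at the 2 days, 1.13 (SE 0.28), did not pass (adjusted p = 0.288). NANOG kept its direction without each day 17 array, with adjusted p = 0.0424 without GFP replicate 1 and between 0.0525 and 0.105 without each of the others. For SOX2, 3 of its 4 probe sets differed by -1.22 to -1.63 at day 7, and 214178_s_at by -0.15.

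Neural genes differed in part. PAX6, an eye and neural transcription factor, was -0.72 at day 7 (adjusted p = 0.535) and rose by 2.16 at day 17 (SE 0.45, adjusted p = 0.0457). The day 17 call of PAX6 was lost without any 1 array other than GFP replicate 1 (adjusted p = 0.0675 to 0.128). In the replicate 1 pair of that day PAX6 differed by 1.05. LHX2 (1.91, with probe sets at 2.92 and 0.91) and the fatty acid binding protein FABP7 (2.05, and 3.72 at day 7, where its probe sets ranged from 0.46 to 5.71) also rose. The intermediate filament gene NES differed by -0.35 (adjusted p = 0.483) and -0.08 (adjusted p = 0.872). Of 27 neural genes, 1 rose and 1 fell at day 7 (1 and 4 over the list alone) and 3 rose and 0 fell at day 17 (5 and 0 over the list alone). The mean was -0.20 at day 7 (camera adjusted p = 0.198) and 0.48 at day 17 (adjusted p = 0.00533, median 0.03), where the adjusted p was 0.631 with an estimated correlation. Without GFP replicate 2 or GFP-PRDM1 replicate 3, the day 17 call was lost at adjusted p = 0.0504 and 0.102. In the pairs of replicates 1, 2 and 3 of day 17 the mean effect on the list was 0.24, 0.64 and 0.54. Without GFP replicate 1 the day 7 mean was -0.29 and passed (adjusted p = 0.0396).

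The trophoblast and amnion list had a mean log2 change of 2.59 at day 7 (camera adjusted p = 1.66e-20) and 2.72 at day 17 (adjusted p = 1.36e-27), and the adjusted p was 0.206 and 0.112 with an estimated correlation. The epithelial list rose at day 7 by a mean of 0.69 (camera adjusted p = 3.51e-07, and adjusted p = 0.0845 with an estimated correlation). At day 17 its mean was 0.34 (adjusted p = 0.000858, and adjusted p = 0.149 with an estimated correlation). Of its 17 genes, 3 rose at day 17 (CLDN4 by 1.02, the desmosome gene DSP by 0.96, RAB25 by 0.76), and 7 rose and 1 fell when adjusted over the list alone. The stromal list had a mean of 0.41 at day 7 (camera adjusted p = 0.130), where IGFBP7 rose by 1.30 (probe sets from 0.40 to 2.14) and THY1 fell by 0.96 (3 rose and 2 fell over the list alone). Its mean was 1.41 at day 17 (adjusted p = 1.03e-14, and adjusted p = 0.112 with an estimated correlation). No camera call at either day for any of the 17 lists held with an estimated correlation. By fry, which tests whether the genes of a list move one way on balance, the trophoblast (adjusted p = 0.0109 and 0.00437) and epithelial (0.00559 and 0.0344) lists passed at both days and the stromal list (0.00437) at day 17. At day 7 the pluripotency list and the list of genes repressed by PRDM1 in B cells passed downward by fry (both 0.0236).

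**Figure D2:**
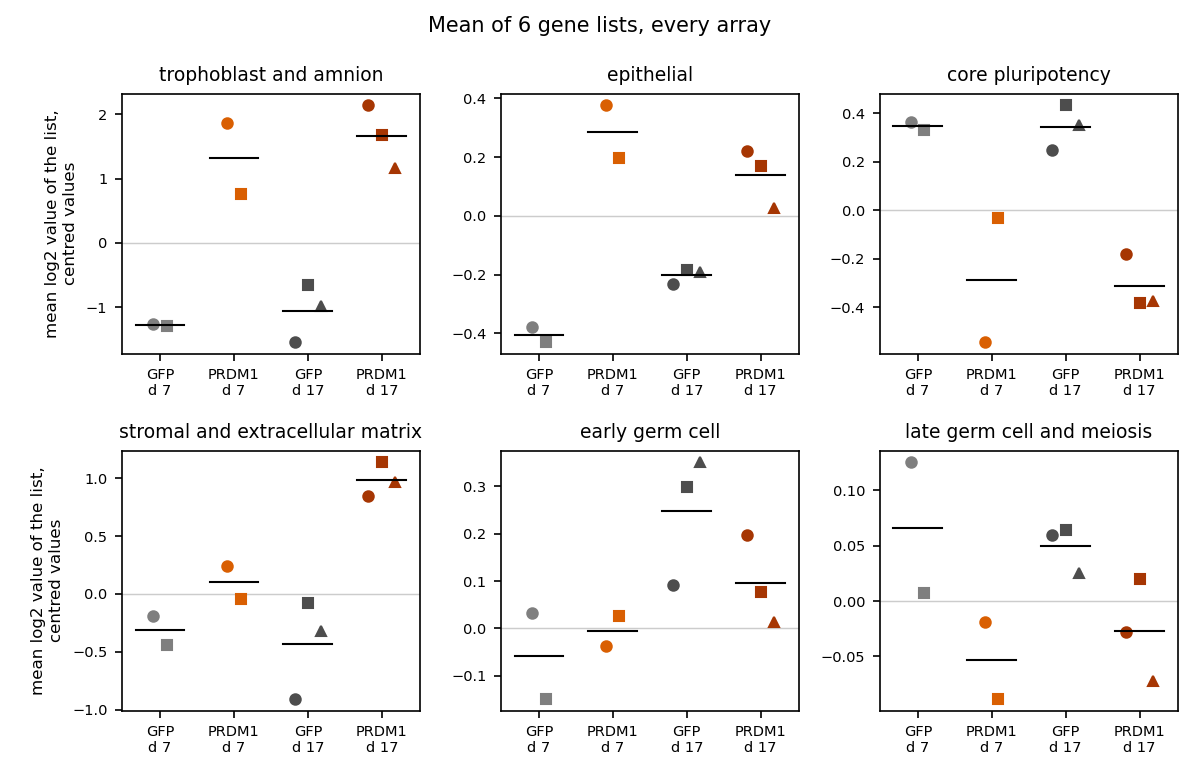
Mean centred log2 value of the genes of each of 6 lists (vertical axis, own scale per panel) on every array, by group (PRDM1 on the axis stands for GFP-PRDM1, d for day), with circle, square and triangle for replicates 1, 2 and 3 and a line at the group mean. The lines of the vectors differ by 2.59 at day 7 and 2.72 at day 17 in the trophoblast and amnion panel, and by 0.05 and -0.15 in the early germ cell panel.

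Of 23 primitive streak and mesoderm genes, 1 rose at day 7 (the homeobox gene ISL1 by 3.34, and 1 over the list alone), with a mean of 0.69 (camera adjusted p = 0.0117, and adjusted p = 0.752 with an estimated correlation). Without GFP-PRDM1 replicate 2 the camera adjusted p was 0.222. At day 17, ISL1 (2.73) and MEOX1 (1.56) rose (2 over the list alone), and the mean of 0.28 did not pass (camera adjusted p = 0.151), while without GFP replicate 2 it was 0.65 and passed (adjusted p = 0.000264). Of 19 endoderm genes, SOX7 rose at both days, by 2.01 and 2.20 (3 and 1 genes over the list alone). The endoderm means of 0.31 (camera adjusted p = 0.268, median -0.05) and -0.28 (adjusted p = 0.477, median 0.06, test direction up) differed in sign from the medians. Cell cycle genes had a mean of -0.25 at day 7 (camera adjusted p = 0.000302) and -0.13 at day 17 (adjusted p = 0.0456), with adjusted p = 0.490 and 0.763 with an estimated correlation. None of the 24 genes passed the limma threshold, over all genes or over the list alone. The day 7 cell cycle call was lost without GFP-PRDM1 replicate 1, where the mean was -0.14 (adjusted p = 0.0597). The day 17 call was lost without GFP replicate 2 (adjusted p = 0.164) or 3 (0.0994) and without GFP-PRDM1 replicate 1 (0.0624) or 2 (0.198). The HOX list had means of 0.01 (camera adjusted p = 0.656, median -0.02) and 0.28 (adjusted p = 0.0121, and adjusted p = 0.763 with an estimated correlation), with none of 19 genes past the threshold, over all genes or over the list alone. Its day 17 call was lost without 4 of the 6 arrays. The mean was 0.12 without GFP replicate 1 (adjusted p = 0.154) and 0.26 without GFP replicate 3 (0.0534). Without GFP-PRDM1 replicate 2 it was 0.19 (adjusted p = 0.136), and without GFP-PRDM1 replicate 3 it was 0.27 (0.0517).

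In the interferon response list, at day 7 IFI6 rose by 2.49 and PSMB9, IFIT1 (-1.71) and RIGI (-1.28) fell, with 2 of 24 genes up and 5 down in all (3 and 7 over the list alone). The mean was -0.24 (camera adjusted p = 0.124), and without GFP replicate 2 it was -0.32 and passed (adjusted p = 0.0436). At day 17, IFI6 (2.66), IRF9 (0.85) and IFI27 (0.46) rose (3 and 0 over the list alone), and the mean of 0.15 did not pass (adjusted p = 0.145, median -0.03), while without GFP-PRDM1 replicate 3 it was 0.23 and passed (adjusted p = 0.0213). Of 17 genes repressed by PRDM1 in B cells, PRKCB (-0.99, with probe sets from -1.98 to -0.04) and PAX5 (-0.69, with probe sets at -1.16 and -0.22) fell at day 7 (2 rose and 5 fell over the list alone, camera adjusted p = 0.117, mean -0.17). Of that list BACH2 (0.72) rose at day 17 (3 and 2 over the list alone, adjusted p = 0.722, mean -0.02). Of 23 DNA and histone methylation genes, KDM6B (0.84) and TET2 (0.78) rose and DNMT3B fell at day 7 (2 and 1 over the list alone), and TET2 (0.82) rose at day 17 (2 and 0 over the list alone). The means were 0.01 (camera adjusted p = 0.948, median -0.08) and 0.03 (adjusted p = 0.438, median -0.01). The p53 and apoptosis list had means of 0.01 (camera adjusted p = 0.425) and 0.02 (adjusted p = 0.568), with GADD45A up by 0.83 at day 7 (1 rose and 1 fell over the list alone at each day). Without GFP replicate 1 its day 17 mean was 0.16 and passed (adjusted p = 0.0384). The WNT, BMP and NODAL target list had means of 0.14 (camera adjusted p = 0.198) and -0.31 (adjusted p = 0.918), with ID2 up by 0.91 at day 7 (1 and 0 over the list alone, and 0 and 1 at day 17). Housekeeping genes had means of -0.10 (camera adjusted p = 0.901) and -0.03 (adjusted p = 0.722, test direction up).

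Many genes moved the same way at both days. Of the genes that rose, 185 were shared (10.7 expected if the calls were independent), including S100P, KRT23, TCIM, VTCN1 and SOX7, and of those that fell, 37 were shared (1.81 expected). The calls are not fully independent, since both days use the same estimate of spread per gene, which by itself favours shared calls. No gene changed in opposite directions at the 2 days. The fold changes of the 2 days correlated at r = 0.63 across genes, which are not independent replicates. Among the 602 genes that rose at day 7, 554 (92.0%) also had a positive value at day 17, with a median of 0.54 there against 1.09 at day 7. The 353 genes that rose at day 17 had a median of 1.21 there and of 1.01 at day 7, where 322 (91.2%) were positive. Of the 472 genes that fell at day 7, 416 (88.1%) were negative at day 17, with a median of -0.24 there against -0.78 at day 7. The 76 genes that fell at day 17 had a median of -0.63 there and of -0.53 at day 7, where 71 (93.4%) were negative. Genes chosen for passing at a given day tend to have larger values at that day. Smaller medians at the other day therefore do not show a weaker effect there. The test of the difference itself passed for 5 genes. COL15A1 differed by 5.15 (SE 0.49, adjusted p = 0.0202) and RND1 by 1.74 (SE 0.18, adjusted p = 0.0202). SYNPR differed by -1.92 (SE 0.19, adjusted p = 0.0202), PLLP by -1.33 (SE 0.14, adjusted p = 0.0202) and the myelin and lymphocyte gene MAL by -1.14 (SE 0.13, adjusted p = 0.0278). COL15A1 lay at 0.09 in GFP-PRDM1 cells at day 7 and at 5.04 at day 17, against -0.11 and -0.31 in GFP cells. With replicate number as a block, 8 genes passed, of which COL15A1 and SYNPR were among these 5, while RND1 (adjusted p = 0.0734), PLLP and MAL (both 0.0744) were not. Without GFP replicate 1 of day 17, 206 genes passed, and each of the 5 calls was lost without at least 1 array.

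**Figure D3:**
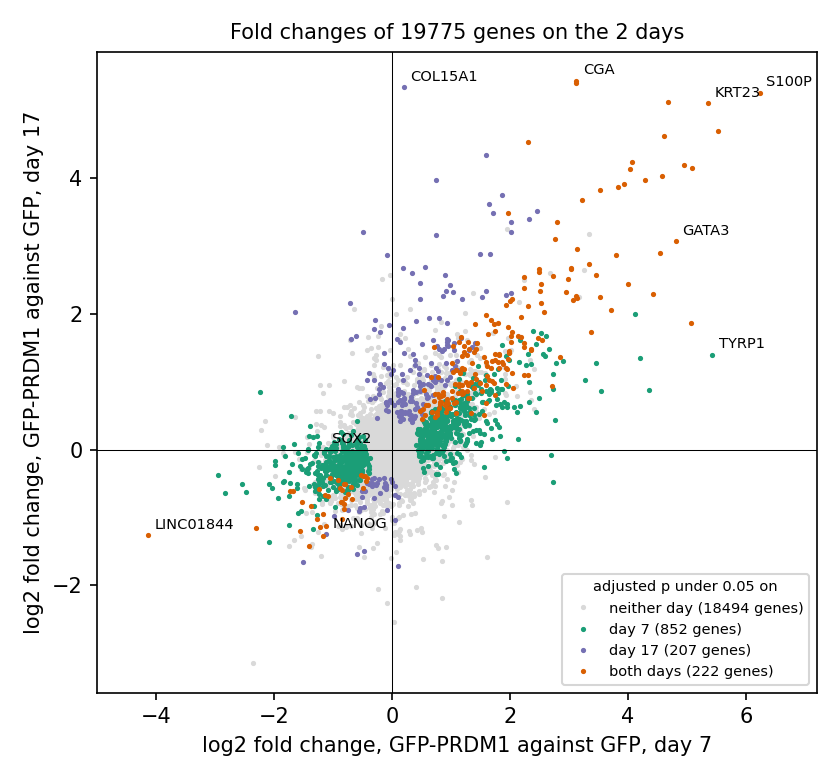
Log2 fold change of GFP-PRDM1 against GFP at day 7 (horizontal axis) and day 17 (vertical axis) for 19775 genes, coloured by the days at which they passed adjusted p under 0.05. 222 genes passed at both days, 852 at day 7 alone and 207 at day 17 alone.

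From day 7 to day 17, 206 genes changed in GFP-PRDM1 cells, of which 118 rose and 88 fell. COL15A1 (4.95), EGFL6 (3.90), the water channel AQP1 (3.73), PAX6 (3.35) and CLEC1B (2.79) rose most. TYRP1 (-4.07), SPARCL1 (-3.65), HCAR3 (-3.29), NPFFR2 (-2.50) and the BMP antagonist SOSTDC1 (-2.46) fell most. With eBayes trend and robust settings the calls of all these genes except EGFL6 were lost (adjusted p = 0.0557 to 0.182). Without each array in turn 2 of these 10 calls, COL15A1 and SPARCL1, were kept, and that of EGFL6 was among the lost. In GFP cells, 1 gene passed, ID3, a BMP-responsive repressor, which rose by 1.23 (SE 0.11, adjusted p = 0.0257), while 1192 genes had an unadjusted p under 0.05. Its call was lost without 3 of the 5 GFP arrays, at adjusted p up to 0.762. With replicate number within a vector as a block, 3 genes passed in GFP-PRDM1 cells and 0 in GFP cells in limma. The count in GFP-PRDM1 cells was 23 without replicate 1 of day 7, and that in GFP cells was 137 without replicate 1 of day 17. Between the days in GFP cells, 5 lists passed camera. The WNT, BMP and NODAL target list had a mean of 0.48 (adjusted p = 5.57e-05, and adjusted p = 0.157 with an estimated correlation) and the early germ cell list of 0.30 (adjusted p = 0.00487, and adjusted p = 0.154 with an estimated correlation). The mesoderm (0.42, adjusted p = 0.0179), endoderm (0.63, 0.0183) and cell cycle (-0.10, 0.0183) lists had adjusted p = 0.877 with an estimated correlation. In 3 of these lists the higher mean at day 17 came from GFP replicates 2 and 3, while replicate 1 lay below both day 7 arrays. Replicates 1, 2 and 3 of day 17 stood at -0.70, 0.86 and 1.00 on the endoderm list (-0.18 and -0.29 at day 7), at -1.05, 0.65 and 0.13 on the mesoderm list (-0.54 and -0.48) and at -0.34, 0.57 and 0.54 on the WNT, BMP and NODAL list (-0.29 and -0.16). In GFP-PRDM1 cells 4 lists passed. These were the stromal list (0.88, adjusted p = 1.62e-08, and adjusted p = 0.339 with an estimated correlation), the neural list (0.58, adjusted p = 0.000520, and adjusted p = 0.442 with an estimated correlation), the interferon list (0.32, adjusted p = 0.000229, and adjusted p = 0.442 with an estimated correlation) and the list of genes repressed by PRDM1 in B cells (0.19, adjusted p = 0.0135, and adjusted p = 0.339 with an estimated correlation). The early germ cell list had a mean of 0.10 there and did not pass (adjusted p = 0.375).

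Replicates 2 and 3 of day 17, of both vectors, stood apart from the other 6 arrays. CHCHD2, a mitochondrial protein gene, lay at 4.24 ± 0.30 (SD, n = 4) in these arrays and at -0.29 ± 0.31 (SD, n = 6) in the others, and in all 8 genes separated the 4 arrays from the other 6 by a gap of at least 1, all higher. QPCT, ZNF542P and PSMD5 had gaps of 2.99, 2.39 and 1.58. Of the 210 splits of the arrays into 4 and 6, 2 separated as many genes, the other, with 17, setting GFP-PRDM1 replicate 1 of day 7 and the GFP-PRDM1 arrays of day 17 apart from the rest. The mean effect of GFP-PRDM1 on the endoderm list was 0.61 in the replicate 1 pair and -0.60 and -0.85 in the other two pairs, on the mesoderm list 1.16, -0.28 and -0.04, on the early germ cell list 0.11, -0.22 and -0.34, and on the pluripotency list -0.43, -0.81 and -0.72. With this split as a term in the fit, 680 genes changed at day 17, with replicate 1 alone 91, and with replicates 2 and 3 alone 471.

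**Figure D4:**
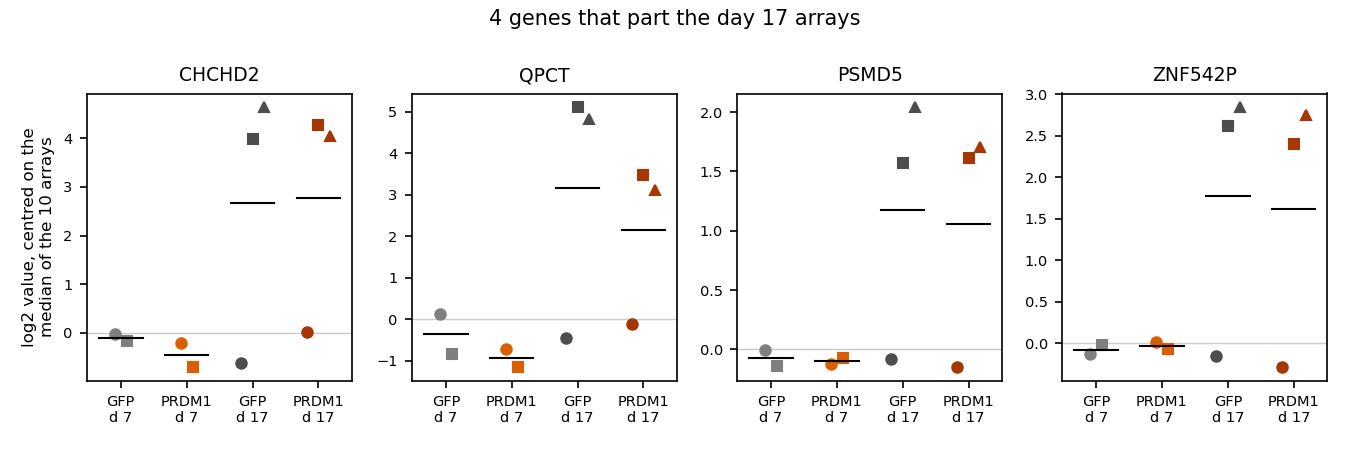
Log2 values (vertical axis, own scale per panel) of CHCHD2, QPCT, PSMD5 and ZNF542P on every array, by group (PRDM1 on the axis stands for GFP-PRDM1, d for day), with circle, square and triangle for replicates 1, 2 and 3 and a line at the group mean. CHCHD2 averages 4.24 in replicates 2 and 3 of day 17 of both vectors and -0.29 in the other 6 arrays.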

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

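The test of the probe sets outside the gene table was chosen only after the values were seen, while the tests of the difference between days were planned. The effect of GFP-PRDM1 differed between days 7 and 17, by the test of the difference itself, for 5 genes. COL15A1 gave a difference of 5.15, RND1 of 1.74, SYNPR of -1.92, PLLP of -1.33 and MAL of -1.14 (log2, day 17 minus day 7). Each of these calls was lost without at least 1 array, with adjusted p up to 0.185 for COL15A1, and all kept their direction. SYNPR lay at 1.41 in GFP-PRDM1 cells at day 7 and at -0.01 at day 17, against -0.49 and 0.01 in GFP cells, and RND1 at -0.49 and 0.22 against 0.90 and -0.13.

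The same test passed by camera for 5 lists. The mean difference was 0.67 for the neural list (adjusted p = 0.000266, and adjusted p = 0.402 with an estimated correlation), 1.00 for the stromal and extracellular matrix list (7.01e-09, and adjusted p = 0.237 with an estimated correlation), 0.12 for the cell cycle list (0.0298, and adjusted p = 0.660 with an estimated correlation), 0.38 for the interferon response list (0.000108, and adjusted p = 0.402 with an estimated correlation) and -0.35 for the epithelial list (0.000833, and adjusted p = 0.237 with an estimated correlation).

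Among 13522 probe sets outside the gene table, with no gene or several genes in the annotation, 58 changed at day 7 (41 higher, 17 lower) and 20 at day 17 (19 higher, 1 lower).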

How the results depend on the processing

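The probe set choices by highest mean and largest SD, the test of every probe set and the settings that divide the day 17 arrays were chosen only after the results were seen. The 5 gene counts moved with the settings below, while in the vector comparison at days 7 and 17 both germ cell lists kept their call, with neither past the threshold, under every alternative run. For lists over time, camera with an estimated correlation and fry were run, and the other alternatives were not. With array quality weights 1862 genes changed at day 7, 926 at day 17, 61 in the difference between days and 11 over time in GFP cells. With every probe set tested the counts of probe sets were 1773, 679 and 404 at day 7, at day 17 and over time in GFP-PRDM1 cells, and 0 over time in GFP cells; with a fold change of at least 1 the gene counts were 463, 234 and 85 in the first 3 of these. With the term for the day 17 replicates they were 680 at day 17 and 10 in the difference. By replicate 1 of day 17 alone they were 91 at day 17, 0 in the difference, 0 over time in GFP cells and 4 in GFP-PRDM1 cells, and by replicates 2 and 3 alone 171, 202 and 791 in the last 3. The difference between days gave 15 genes with the highest-mean probe set, 3 without _s_at, _x_at and _a_at probe sets, 0 with trend and robust eBayes and 8 with the replicate block. Over time in GFP cells quantile normalization gave 8 genes, and each of no _s_at, _x_at or _a_at probe sets, the largest-SD probe set, trend and robust eBayes, only the groups compared, and the replicate block gave 0. Over time in GFP-PRDM1 cells the counts were 134 with quantile normalization, 313 with the largest SD, 13 with trend and robust eBayes and 3 with the block. Where limma gave 0 genes, 1096 to 1630 genes in the difference and 614 to 1770 over time in GFP cells had an unadjusted p under 0.05, as did 2456 probe sets there with every probe set tested. Leaving out each array gave 106 to 1037 genes at day 7, 157 to 774 at day 17, 0 to 206 in the difference, 0 to 137 over time in GFP cells and 23 to 307 in GFP-PRDM1 cells. By replicate 1 of day 17 alone the endoderm list reversed to 0.61 and the WNT, BMP and NODAL list to 0.23. Fewer arrays, a higher threshold and more units tested follow from those settings, and otherwise the cause was not tested. Where 1 array stands for a group, it is assumed to vary like the other groups.

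Across the other settings for named genes, 1696 values stayed on the same side of the threshold, which includes genes that passed in neither fit. A call was lost in 406, gained in 12 and reversed in 0. For lists 567 values stayed on the same side, 37 lost a call, 9 gained one and 2 reversed. Without each array in turn 12 of 45 named calls at day 7 and 17 of 37 at day 17 were kept, and the lost calls all kept their direction, with adjusted p up to 0.287 (PRDM14) and 0.151 (ISL1). With the replicate block, no list call changed at day 17, and 1392 genes changed at day 7. The 40th percentile filter removed no gene, so it tests nothing, and the pseudocounts were not run because the values are logarithms. Centred values hold no signal over background, so what low signal limits was not measured.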

Other observations

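The added lists of this part and the tests that weigh explanations, except the count over splits of the day 17 arrays, were chosen only after the results were seen, while the SOX2 comparisons at each day and between the days were planned. The placental, amnion and antigen presentation lists were assembled after some of their members were seen among the largest changes, so the counts describe these genes and do not test the groups. Of 14 amnion genes, 3 of them also in the trophoblast and amnion list, 7 rose at day 7 (mean log2 change 2.67) and 9 at day 17 (mean 2.54). Of 20 syncytiotrophoblast genes, 5 of them in that list, 7 rose and 1, KISS1, fell at day 7 (mean 1.17), and 10 rose at day 17 (mean 1.84). At day 17 these included the steroid synthesis genes HSD3B1 (3.69) and CYP11A1 (2.89) and the fusion regulator GCM1 (3.41). Of 13 extravillous trophoblast genes, 1 (DIO2) rose at day 7 (mean 0.18) and 4 at day 17 (mean 0.32), while HLA-G differed by -0.42 at day 17 without passing. Of 13 cytotrophoblast genes, 4 rose at day 7 (mean 0.85) and 3 at day 17 (mean 0.63).

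Beside PSMB9 (-2.47) and IDO1 (-2.83), which led to the list of 15 immunoproteasome and antigen presentation genes, 8 of its members fell at day 7, among them the proteasome subunit PSMB8 (-1.85), the activator PSME1 (-1.06) and the peptide transporter TAP1 (-0.91), and 0 rose. The mean over the list was -0.98 at day 7 and -0.24 at day 17, where none of its genes passed in limma, while 3472 of all genes had an unadjusted p under 0.05. Of the 15, 3 are in a fixed list.

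The rise of trophoblast and amnion genes was weighed against 3 technical explanations. RNA of human fibroblasts would raise stromal genes as much, but at day 7 the trophoblast mean exceeded the stromal mean by 2.18 (SE 0.431). At day 17, where stromal genes rose too, it did so by 1.31 (SE 0.324). The feeders were mouse cells, and how far probe sets for human genes read their RNA was not measured. These values therefore cannot decide on feeder RNA. A lower share of undifferentiated cells alone need not raise all other lineages alike, so unequal rises cannot decide on it. The smallest of 6 differences of the trophoblast mean from the neural, mesoderm and endoderm means was 1.90. It was that from the mesoderm list at day 7, and its SE over arrays, 0.689, rests on 2 arrays per vector. A batch among the day 17 arrays does not account for the rise, since the smaller of the within-batch effects was 2.24. A differentiation toward trophoblast or amnion with GFP-PRDM1 may account for the pattern, a hypothesis that none of these values tests directly and that staining of GFP-positive cells for proteins such as CGA and VTCN1 would test.

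Replicates 2 and 3 of day 17 standing apart had no biological explanation in the design. The median of the batch term over all genes was 0.0300. It cannot decide on a scaling difference, since the deposited array medians all lay within 0.0247 of 0. Housekeeping genes averaged 0.158 and 0.179 in GFP and 0.144 and 0.112 in GFP-PRDM1 replicates 2 and 3 of day 17. In the other arrays they lay between -0.120 and 0.032. A gained or lost whole chromosome in most cells is argued against by a largest chromosome median of 0.0601, for chromosome 20, among 23 chromosomes. That median cannot decide on a change in part of a chromosome or in few of the cells. The hypoxia genes averaged 0.429, with 11 of 15 positive, as lower oxygen or denser culture in those samples would also give. The SE of 0.157 is taken over the genes and does not measure the spread between arrays. In the vector comparison the same 15 genes had means of -0.10 at day 7 and -0.01 at day 17. Another stock or batch of cells cannot be told apart from these, since 3 genes separated the arrays by 2 or more, as another stock would also give, and no label names a stock.

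SOX2 was lower at day 7 and differed by 0.00 at day 17, though the difference between the days did not pass (1.13, adjusted p = 0.288). A lower PRDM1 signal at day 17 stays open as an explanation, and the probe sets may read the cells' own gene and not the vector's transcript. The effect was lower at day 17 by over 2 standard errors for 217192_s_at, which had the smallest p at day 7 (-1.45, SE 0.173, adjusted p = 0.0512), and 235668_at (-0.78, SE 0.303, adjusted p = 0.548) but not for 228964_at (-0.80, SE 0.680, adjusted p = 0.859). None of the 3 passed the adjusted threshold in limma, and in GFP-PRDM1 cells 228964_at lay at 0.06 at day 7 and 0.46 at day 17 and 235668_at at 0.14 and 0.01. The batch among the day 17 arrays stays open too, since the replicate 1 pair gave -0.348 and is 1 pair only, against 0.22 and 0.14 in the others. The SE of that pair's difference from the day 7 effect of -1.13 was 0.373.

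Of the 10 splits of the 6 day 17 arrays into 3 and 3, 1 called as many genes as the real one, which is the real split itself, with 429 genes against 4 for the highest other, and 10 splits are too few for a share under 0.05. The other 3 splits that part all pairs called 0 genes in limma, with 250 to 741 genes at an unadjusted p under 0.05, and the split with 4 genes keeps the pairs of replicates 1 and 2 together.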
